A study of Homo sapiens with 8 samples.

How the data were processed

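RNA from 8 cultures of the thyroid cancer cell line RO82_W1 was measured on 4 dual-channel oligonucleotide arrays, with 2 cultures labelled as biological replicates in each of 4 groups. Per the labels' protocols, cells received 0.05 µg of the PGl3 control plasmid, of a PRC plasmid or of an ERRalpha plasmid, or 0.05 µg of both plasmids, and were compared after 48 h. The wording leaves open whether the combined transfection held 0.05 µg in all or 0.05 µg of each plasmid. Total RNA was extracted with a column kit, its integrity was checked, and it was amplified and labelled with Cy3 or Cy5, per the labels' protocols.

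Mean spot intensity and median local background intensity in each channel are pixel brightness as scanned, extracted with Agilent Feature Extraction 10.5.1.1, per the file headers. A further pair of intensity columns was background-subtracted, detrended and dye-normalized within the array by the same software, per the file headers, and was used only in an alternative. Flag columns give 0 or 1 for a spot well above background, an outlier or saturated, per the file headers. The probe coordinates are those of the hg18 build named in the file headers. The headers gave 1 scan time, 1 array design and 1 protocol for all 4 arrays, so a block for slide or scan, which had been planned, could not be fitted.

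The deposited series value table holds log2 values for 11679 probes and 22 control features. How the authors made it is not stated in any label. Each of its 8 columns matched the log2 mean intensity of 1 scanner channel with a slope of 1.00 and a correlation across probes of at least 0.9999, after a constant was taken off. For 7 of the 8 columns, the matching channel was that of another sample than the column's name, and for 5 it was that of another group. The columns named control or ERRalpha held Cy5 channels, and those named PRC or PRC+ERRalpha held Cy3 channels. Read by column name, the table thus mixes groups and sets Cy3 against Cy5 in PRC or PRC+ERRalpha against control. It stays in the counts of alternatives below, but a turn, pass or lost call there does not test a plasmid. The constant behind each column remained unknown. The column medians were -0.12 for control replicate 1, -0.12 for control replicate 2, -0.11 for PRC replicate 1, -0.12 for PRC replicate 2, -0.11 for ERRalpha replicate 1, -0.12 for ERRalpha replicate 2, -0.10 for PRC+ERRalpha replicate 1 and -0.12 for PRC+ERRalpha replicate 2. The comparisons therefore used the scanner files, with each channel assigned by its label's dye and by the order of the 2 samples in the file name. PPRC1, the gene of the PRC plasmid, was high in the 4 channels so assigned to a PRC plasmid and in no other.

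The spots were read with R 4.3.3, limma 3.58.1, data.table (version 1.17.8) and statmod 1.5.0. Each array held 43376 spots that were not controls, for 41000 distinct probes, and replicate spots were averaged (264 probes with 10 spots each). Outlier spots were set to missing. Median intensity ran from 113 to 321 between the 8 channels, and median background from 21 to 69. No spot was saturated. The share of probes well above background ran from 51.0% to 65.9%, and both channels of the array with ERRalpha replicate 2 and PRC replicate 2 gave 51.0%. Background was corrected by normexp with an offset of 50, dyes were balanced within arrays by loess, and average intensities were made equal between arrays by quantiles. Probes well above background in at least 2 of the 8 channels were kept, which left 26861 probes (65.5%), 54 of them with a missing value. The precision is limited by the number of arrays.

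Names came from the files' accessions and symbols, matched to the RefSeq table of GRCh38.p14, which was used for names only. An accession named 23958 probes, a current symbol 2755, an older symbol 1032 and another accession 32, while 13223 stayed without a current name. XIST and Y-linked genes were left out.

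Log2 channel intensities were fitted with limma's separate-channel model, with group and dye as terms and the array as a random block (intraspot correlation 0.511, 3 residual and 5.55 prior degrees of freedom). Each group lay once in each dye, so group and dye were balanced. ERRalpha and control never shared an array, nor did PRC+ERRalpha and PRC, so those differences went through the loop of arrays. A fitted difference weighs each sample by its partner on the array, and it can differ from the difference of 2 group means. Levels per group are given as the mean and SD of 2 dye-adjusted log2 values. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over all kept probes. The 9 contrasts were each transfection against control, the 3 differences between transfected groups, the average effect of each plasmid, and the interaction (the effect of the PRC plasmid with ERRalpha minus that without). Differences are on the log2 scale with the standard error of the fit.

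Of 25 gene lists fixed before the data were examined, 24 had at least 5 measured genes. The list of PRC, ERRalpha and their relatives had fewer and was not tested. Each gene took its brightest probe (13382 genes). The lists were tested against all other genes with limma's camera, with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. The same test with an estimated correlation, and limma's fry, were run beside it. No list passed 0.05 with an estimated correlation, nor by fry, in any of the 9 contrasts. The "list value" below is the mean log2 difference of the list minus that of all other genes. Counts of members adjusted over a list alone are given for lists called in the same data and are no further support for them.

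The genes to name were also fixed before the data were examined. They were PPRC1 and ESRRA; for each comparison with control, up to 8 named genes with the largest rise and 8 with the largest fall among those past the threshold whose 2 treated samples both lay on the same side of both controls, or the 4 with the smallest p in a direction where none passed; up to 3 members of each list past the threshold; LDHA, LDHB, PDK4, CYCS, TFAM, NRF1 and SLC16A1; and up to 4 genes in each direction for the other contrasts. Probes without a current gene name lay outside this rule, and those named here were chosen after their values were seen.

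The model was tested on simulated data with the real design and 200 changed probes. In the PRC, ERRalpha and PRC+ERRalpha comparisons with control it called 98, 100 and 94% of changes of 1 log2 unit and 26, 28 and 32% of changes of 0.5, with 4, 8 and 9 unchanged probes called. The 200 included 50 probes changed by 2 and 50 by 3 log2 units. In the data 2, 1 and 6 probes passed in these comparisons, so the adjusted threshold was stricter there, and these shares do not give the power in the data.

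The alternatives fixed before the data were examined were Agilent's processed intensities, no background subtraction, loess only, quantiles over all channels without loess, no filter, a filter on all 8 channels, no dye term, a replicate block, no array block, log ratios only (1 residual degree of freedom), an intensity trend in the variance, the series value table by its column names, the mean of a gene's probes, an estimated correlation, and leaving out each sample in turn. Loess only leaves average intensities unequal between arrays. No array block sets the intraspot correlation of 0.511 aside, and no dye term leaves dye differences in the spread. A call that ended under these settings does not by itself show that the difference was absent. Added after seeing the data were the value table with each column placed by its scanner channel, the array with the lowest share above background left out, and the lists in the other contrasts. With a sample or array left out, or with a replicate block, the intraspot correlation could not be estimated and the value of 0.511 was kept. The lone sample of a group was then assumed to vary like the other groups. Without that array PRC and ERRalpha keep 1 sample each, so calls gained there do not show changes that the array had hidden.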

Results

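Gene expression was measured in 8 cultures of RO82_W1, a human thyroid cancer cell line, 48 h after transfection. Of the 4 groups, 2 cultures each received the control plasmid PGl3 (a luciferase reporter vector), a plasmid for PRC, a plasmid for ERRalpha, or both. PRC, encoded by PPRC1, is a coactivator related to PGC-1alpha. ERRalpha, encoded by ESRRA, is an orphan nuclear receptor that acts on mitochondrial and energy genes. The comparisons asked which transcripts differed from control cells with each plasmid and with both, as the series design states. Between 51.0% and 65.9% of the probes lay well above background in each channel, and 26861 probes were tested.

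The PPRC1 probe (A_23_P127079, hg18 chromosome 10, 103899679 to 103899738) separated the samples by the PRC plasmid. Its log2 intensity was 11.58 ± 0.14 (SD, n = 2) in control, 13.70 ± 0.56 in PRC, 11.74 ± 0.03 in ERRalpha and 14.06 ± 0.45 in PRC+ERRalpha cells. All 4 samples with the PRC plasmid, from 13.31 to 14.38, lay above the 4 without it, which reached 11.76. Averaged over the presence of ERRalpha, PPRC1 rose 4.67-fold with the PRC plasmid (log2 difference 2.22 ± 0.13 SE, adjusted p = 6.90e-04). The call ended without PRC+ERRalpha replicate 1 (log2 difference 1.97, adjusted p = 0.0703). It also ended with loess only (adjusted p = 0.293) and with Agilent's processed signals (adjusted p = 0.608), the ends of its range over all alternatives being 1.43e-11 and 0.608. In the deposited value table read by its column names, 7 of whose 8 columns matched another sample's scanner channel, the difference turned to -0.20. The ESRRA probe (A_23_P1585, chromosome 11, 63840691 to 63840750) gave 11.06 ± 0.12 (SD, n = 2) in control, 11.16 ± 0.07 in PRC, 11.15 ± 0.02 in ERRalpha and 11.19 ± 0.07 in PRC+ERRalpha cells. Its differences from control of 0.08 ± 0.08 (SE), 0.10 ± 0.09 and 0.15 ± 0.08 did not pass the threshold. The labels do not say which part of ESRRA the plasmid held, and a probe outside that part checks nothing.

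**Figure D1:**
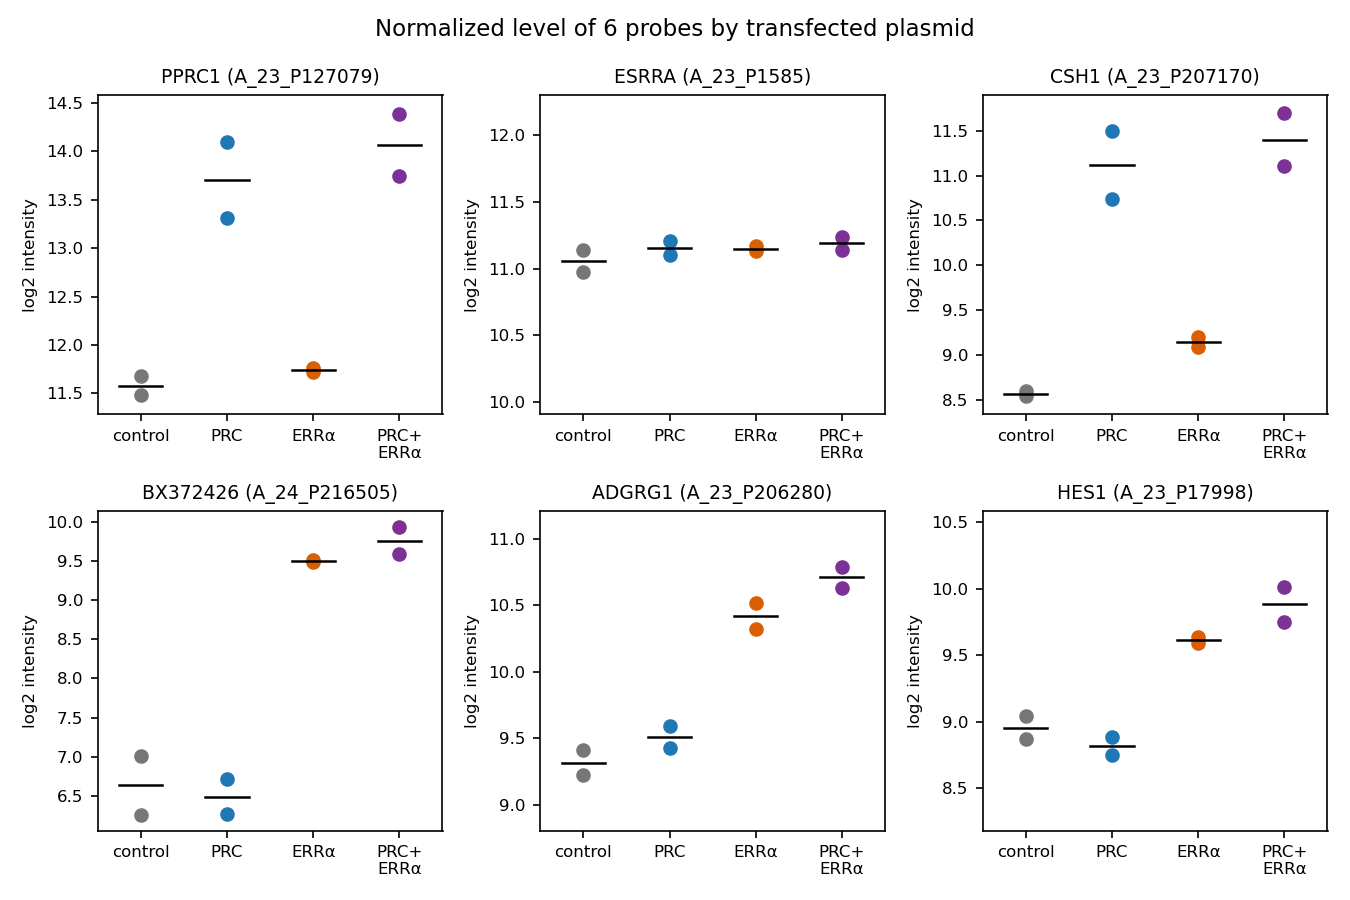
Normalized, dye-adjusted log2 intensity of 6 probes, 1 panel each, by transfected plasmid; points are the 2 samples of a group and bars their mean. PPRC1 and CSH1 lie higher in the 4 samples with the PRC plasmid, BX372426, ADGRG1 and HES1 lie higher in the 4 with the ERRalpha plasmid, and ESRRA means lie between 11.06 and 11.19.

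In cells with the PRC plasmid alone, the probes that rose against control were an overlapping pair annotated to CSH1, the placental lactogen gene of the growth hormone cluster. Whether they read the gene's own transcript was not shown. Probe A_23_P207170 (hg18 chromosome 17, 59326008 to 59326067) rose 5.20-fold (log2 difference 2.38 ± 0.20 SE, adjusted p = 0.0171), from 8.56 ± 0.04 (SD, n = 2) to 11.12 ± 0.54. Probe A_24_P211044 (59326005 to 59326062) rose 5.41-fold (2.43 ± 0.20, adjusted p = 0.0171). The other tested CSH1 probe (A_23_P207174), well above background in 3 of the 8 channels, gave 0.06 ± 0.13. PPRC1 itself was 3.92-fold higher (1.97 ± 0.21) in this pair of groups, with both PRC samples above both controls, but missed the threshold (adjusted p = 0.0774). It passed without PRC replicate 1 (2.69, adjusted p = 0.00147), PRC replicate 2 (1.54, 0.00260) or either ERRalpha replicate (1.96, 0.0354). It also passed with an intensity trend (adjusted p = 0.00662), a replicate block (0.0472), a filter on all channels (0.0457) and without the array of ERRalpha replicate 2 and PRC replicate 2 (8.95e-08), the highest adjusted p of all alternatives being 1.00. No probe passed as lower. The named genes with the smallest p in that direction were CCDC71 (-0.48 ± 0.09), the caspase gene CASP8 (-0.44 ± 0.08), APOL6 (-0.87 ± 0.17) and FBXO34 (-0.57 ± 0.11), each with an adjusted p of 0.993. Other probes gave -0.27 for CCDC71, -0.16 for CASP8 (the brighter probe), -0.10 for APOL6, and -0.05 and 0.02 for FBXO34. Without the array of ERRalpha replicate 2 and PRC replicate 2, APOL6 (adjusted p = 0.00480) and FBXO34 (0.00271) passed as lower, and FBXO34 did so without PRC replicate 2 (0.0315). By limma, 2 probes passed as higher and 0 as lower, against 241 higher and 697 lower at an unadjusted p under 0.05, where chance alone gives 1343. The CSH1 calls ended without control replicate 1 (adjusted p = 0.264 for A_23_P207170 and 0.295 for A_24_P211044), without control replicate 2 (0.176 for both), or without either PRC+ERRalpha replicate (0.0726 for both). In the value table, A_24_P211044 gave 0.92 (adjusted p = 0.135). The other alternatives that ended both calls were no background subtraction (adjusted p = 0.0551), loess only (0.657), no filter (0.0836), no dye term (0.0711), no array block (0.113), log ratios (0.659) and Agilent's processed signals (1.00), and the whole range was 1.98e-10 to 1.00. With loess only, the median over all probes moved from -0.02 to 0.13.

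Genes of respiratory Complexes II to IV, cytosolic ribosomal proteins and cholesterol synthesis lay slightly above other genes in the PRC comparison, while the Complex I list did not pass, and stress and interferon genes lay slightly below. Of the 26 measured genes of Complexes II to IV, 19 were above 0 (median 0.06, list adjusted p = 0.0102), among them COX5A (0.28 ± 0.10), UQCRFS1 (0.17 ± 0.08) and COX7A2 (0.18 ± 0.09), all respiratory chain subunits, but the list value turned from 0.07 to -0.09 in the value table read by column name. Of 84 cytosolic ribosomal protein genes, 49 were above 0 (median 0.04, adjusted p = 0.0107; RPLP1 0.33 ± 0.11, RPL22L1 0.24 ± 0.09, RPS10 0.21 ± 0.09), but the list value turned from 0.04 to -0.04 with loess only and to -0.37 in that table. Cholesterol synthesis genes were above 0 in 17 of 23 (median 0.06, adjusted p = 0.0384; INSIG1 0.16 ± 0.09, SQLE 0.18 ± 0.11, LSS 0.16 ± 0.10). Genes of the integrated stress and unfolded protein response were below other genes (20 of 30 below 0, median -0.09, adjusted p = 0.0166), among them STC2 (-0.42 ± 0.12), the asparagine synthetase gene ASNS (-0.39 ± 0.11) and DDIT4 (-0.22 ± 0.09). Interferon response genes (23 of 34 below 0, median -0.06, adjusted p = 0.0107; IFI44L -0.26 ± 0.08, OAS3 -0.38 ± 0.13, PARP9 -0.29 ± 0.10) and heat shock genes (17 of 21 below 0, median -0.08, adjusted p = 0.0384; HSPA6 -0.27 ± 0.12, HSP90AA1 -0.25 ± 0.11, DNAJB1 -0.18 ± 0.09) were below too, although in that table the heat shock test pointed upward, with a list value of -0.00. Each list gene is read by its brightest probe, and other probes often gave less: 0.11 for COX5A, 0.09 for UQCRFS1, 0.06 to 0.18 for RPS10, -0.12 to -0.02 for LSS, -0.07 for STC2, 0.02 for OAS3 and -0.23 to -0.03 for HSP90AA1. The other RPLP1 probe gave slightly more (0.36). In these 6 lists, 0 members passed by limma over all genes and 0 adjusted over the list alone. Without the array of ERRalpha replicate 2 and PRC replicate 2, OAS3 (adjusted p = 0.00879), STC2 (0.0143) and HSPA6 (0.0480) passed over all genes, and in the value table ASNS did (0.0115). RPLP1 (-0.51, adjusted p = 0.0254) and RPS10 (-0.37, 0.0222) passed by limma in that table as lower, opposite to the values above. Read by column name, its PRC columns hold Cy3 and its control columns Cy5 channels, so passes and turns there do not test the PRC plasmid. In the main fit, at an unadjusted p under 0.05, 1 gene of Complexes II to IV and 4 ribosomal genes were higher, and 5 interferon, 4 integrated stress and 1 heat shock genes were lower. With an estimated correlation, 0 of the 6 lists passed: adjusted p = 0.535 for Complexes II to IV, 0.519 for cytosolic ribosomal proteins, 0.597 for interferon response, 0.572 for both stress lists and 0.691 for cholesterol synthesis. Of 24 alternatives, 11 ended the interferon call, 8 those of cholesterol and heat shock genes, 7 those of Complexes II to IV and ribosomal proteins and 6 that of stress genes. The count of 6 fell to 2 without control replicate 2 and to 1 without either PRC replicate. The list value turned from -0.07 to 0.02 for interferon genes without control replicate 1, from -0.08 to 0.02 for stress genes without PRC replicate 1 and from 0.06 to -0.01 for cholesterol genes without control replicate 2.

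In the PRC comparison, the genes of lactate and mitochondrial metabolism fixed for naming did not pass. LDHA gave -0.22 ± 0.12 (SE) and LDHB -0.20 ± 0.11, both subunits of lactate dehydrogenase. The mitochondrial transcription factor gene TFAM gave -0.13 ± 0.10, NRF1 -0.04 ± 0.08, the lactate transporter gene SLC16A1 -0.10 ± 0.08 and cytochrome c (CYCS) 0.05 ± 0.11. Other probes gave -0.24 and -0.01 for LDHA, -0.01 for TFAM (a pair) and -0.15 for CYCS. In the value table read by column name LDHB passed (-0.29, adjusted p = 0.0406), but the PRC and control columns there differ in dye. PDK4, whose product inhibits pyruvate dehydrogenase, lay near background, with 4 of 8 channels above it.

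In cells with the ERRalpha plasmid alone, 1 probe passed against control, and it lies near the ESRRA probe. The called probe is A_24_P216505 for the expressed sequence tag BX372426 (hg18 chromosome 11, 63838792 to 63838849). It lies 1842 bp from the ESRRA probe, and its coordinates are listed in descending order where those of the ESRRA probe ascend. Whether it lies within the ESRRA gene was not determined. It carries no current gene name and was chosen after its values were seen. Its level was 6.64 ± 0.54 (SD, n = 2) in control and 9.50 ± 0.02 in ERRalpha cells, where it rose (adjusted p = 0.00554). It was well above background in 1 of 2 control and in 2 of 2 ERRalpha samples, so the size of the rise against control is not known: over the alternatives the log2 difference ran from 2.37 to 5.12, the latter with Agilent's processed signals. In PRC cells it was above background in 0 of 2, and against them it was at least 7.32-fold higher in ERRalpha cells. Genes with the smallest p as higher were ADGRG1, an adhesion G protein-coupled receptor (1.02 ± 0.11, adjusted p = 0.146), HES1, a transcriptional repressor downstream of Notch (0.76 ± 0.11, adjusted p = 0.798), SPDEF (0.54 ± 0.12) and HOXD10 (0.49 ± 0.11). None of the 4 passed, and each had both ERRalpha samples above both controls. The second probes of ADGRG1 (0.37 ± 0.11) and HES1 (0.51 ± 0.11) gave smaller values. ADGRG1 passed with an intensity trend (adjusted p = 0.0170) and without the array of ERRalpha replicate 2 and PRC replicate 2 (0.00913). As lower, OAS3 (-0.57 ± 0.14), MAST1 (-0.46 ± 0.11), G0S2 (-0.49 ± 0.12) and LGALS7 (-0.49 ± 0.13) did not pass either. Other probes gave -0.01 and 0.10 for LGALS7 and -0.03 for OAS3. By limma, 1 probe passed as higher and 0 as lower, against 115 higher and 193 lower at an unadjusted p under 0.05. The BX372426 call ended without either PRC+ERRalpha replicate (adjusted p = 0.770), with loess only (0.112), no array block (0.0686), log ratios (0.338) and Agilent's processed signals (1.00), within a range of 8.73e-10 to 1.00, and a filter on all 8 channels removed the probe. With loess only, the median over all probes moved from -0.01 to 0.21.

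Small list shifts were called in the ERRalpha comparison, with interferon response genes lower and those of Complexes II to IV, hypoxia and cholesterol synthesis higher. Of 34 interferon response genes, 25 were below 0 (median -0.08, list adjusted p = 4.47e-06), among them OAS3 (-0.57 ± 0.14), MX1 (-0.36 ± 0.10) and IFI44 (-0.33 ± 0.10), although the list value turned from -0.10 to 0.24 in the value table read by column name. Complexes II to IV had 19 of 26 above 0 (median 0.06, adjusted p = 0.0183; COX5A 0.27 ± 0.11, UQCRFS1 0.18 ± 0.09, COX7A2 0.14 ± 0.10), but -0.01 as the list value in that table. Hypoxia genes had 17 of 27 above 0 (median 0.04, adjusted p = 0.0263), among them the lipase inhibitor gene ANGPTL4 (0.34 ± 0.10), ADM (0.23 ± 0.10) and HIF1A (0.18 ± 0.11). Cholesterol synthesis genes had 18 of 23 above 0 (median 0.08, adjusted p = 0.0119, with FDFT1 0.16 ± 0.10 and SQLE 0.19 ± 0.12), but -0.04 in that table. There the columns named ERRalpha hold channels of PRC and PRC+ERRalpha samples, so these turns do not test the ERRalpha plasmid. The 9 measured epithelial markers were all below 0 (median -0.10, adjusted p = 0.0119), with ESRP2 (-0.17 ± 0.10), ESRP1 (-0.19 ± 0.12) and the keratin gene KRT19 (-0.19 ± 0.13). Their mean difference from the mean of all samples was 0.07 in ERRalpha replicate 1 and -0.13 in replicate 2, against 0.10 and 0.11 in the controls. PRC replicate 2, on the array of ERRalpha replicate 2, gave -0.10 and PRC replicate 1 gave 0.03, so an effect of that array is not told apart from the plasmid. In these 5 lists, 0 members passed by limma over all genes and 0 adjusted over the list alone. Other probes gave 0.09 for COX5A, 0.04 for UQCRFS1 and -0.03 for OAS3. With an estimated correlation, 0 lists passed, each with an adjusted p of 0.685. Of 24 alternatives (22 for epithelial markers), 14 ended the calls of Complexes II to IV and hypoxia genes, 10 those of cholesterol genes and epithelial markers and 6 that of interferon genes. The count of 5 fell to 1 without control replicate 2 or ERRalpha replicate 2 and to 3 without any 1 of the other 6 samples. The cholesterol list value turned from 0.06 to -0.03 without control replicate 2, and the epithelial one from -0.11 to 0.01 without ERRalpha replicate 2. The textbook ERRalpha target genes, 24 measured, gave a median of 0.02 (adjusted p = 0.881), and LDHA (-0.05 ± 0.13), LDHB (-0.16 ± 0.12), CYCS (0.01 ± 0.12), TFAM (-0.13 ± 0.11), NRF1 (0.07 ± 0.09), SLC16A1 (-0.00 ± 0.09) and PDK4 (0.02 ± 0.09) did not pass. Other probes gave -0.09 and 0.07 for LDHA, -0.08 and -0.06 for TFAM and 0.03 for CYCS.

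With both plasmids, 6 probes rose against control, those of CSH1 (a pair), PPRC1, ADGRG1, HES1 and BX372426. CSH1 signal rose 6.38-fold by A_23_P207170 (log2 difference 2.67 ± 0.20 SE) and 6.67-fold by A_24_P211044 (2.74 ± 0.20), each with an adjusted p of 0.00328. PPRC1 rose 4.82-fold (2.27 ± 0.21, adjusted p = 0.0152). ADGRG1 (A_23_P206280, hg18 chromosome 16, 56256277 to 56256336) rose 2.65-fold (1.40 ± 0.10, adjusted p = 0.00328), from 9.32 ± 0.13 (SD, n = 2) to 10.71 ± 0.11. HES1 (A_23_P17998, chromosome 3, 195338870 to 195338929) rose 1.93-fold (0.95 ± 0.10, adjusted p = 0.0351), from 8.96 ± 0.12 to 9.88 ± 0.19. BX372426 rose (adjusted p = 0.00155), by an amount that is not known, since 1 of 2 controls was well above background and the log2 difference ran from 2.67 to 5.30 over the alternatives, and was at least 8.76-fold higher than in PRC cells. For each of these probes, both PRC+ERRalpha samples lay above both controls. The second probes of ADGRG1 (0.58 ± 0.10) and HES1 (0.57 ± 0.10) had an adjusted p of 0.169 each. No probe passed as lower, and the smallest p in that direction belonged to IER3 (-0.74 ± 0.10), MMP10 (-0.57 ± 0.08), the heat shock gene HSPA6 (-0.82 ± 0.12) and ANXA2 (-0.53 ± 0.08), with adjusted p from 0.116 to 0.131. Other ANXA2 probes gave -0.44 and 0.03. These 4 genes passed as lower with an intensity trend (adjusted p = 0.0213 to 0.0256) and without the array of ERRalpha replicate 2 and PRC replicate 2 (4.70e-04 to 0.0111), and all but HSPA6 in the value table read by column name (0.00284 to 0.0272). In that table the columns named PRC+ERRalpha hold Cy3 and those named control Cy5 channels, so the passes there do not test the plasmids. By limma, 6 probes passed as higher and 0 as lower, against 2348 higher and 2261 lower at an unadjusted p under 0.05. Chance gives 1343 for independent probes, but probes of a sample can vary together, and the 9 contrasts ran from 308 to 4609. The excess over 1343 is therefore not itself evidence of a plasmid effect.

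Whether the 6 probes with both plasmids passed the threshold depended on single samples. With 1 sample fewer the fit also has less to estimate the spread from, so a lost call is not itself a lost difference. Over all alternatives the log2 differences ran from 0.84 to 1.55 for ADGRG1, 0.72 to 1.09 for HES1 and 1.26 to 2.90 for PPRC1. They ran from 2.32 to 3.26 for CSH1 by A_23_P207170, 1.38 to 3.34 by A_24_P211044 and 2.67 to 5.30 for BX372426. Without PRC+ERRalpha replicate 1 the count was 0, with an adjusted p of 0.122 for each of the 6 probes. Without control replicate 2 it was 3, and the calls of ADGRG1 (adjusted p = 0.489), CSH1 (0.360 and 0.307), HES1 (0.771) and PPRC1 (0.567) ended. Without PRC+ERRalpha replicate 2, those of ADGRG1 (0.205), BX372426 (0.282), CSH1 (0.0773), HES1 (1.00) and PPRC1 (0.146) ended. Without control replicate 1, HES1 (0.160) and PPRC1 (0.0776) no longer passed while the count was 16, and without either PRC replicate the count was 12. All 6 calls also ended with Agilent's processed signals (0.535), loess only (0.131 to 0.468) and log ratios (0.0805 to 1.00), while their log2 differences stayed above 0 in all alternatives run. The call of HES1 ended with no filter (0.0741), no dye term (1.00) and no array block (0.473), and that of PPRC1 with no filter (0.0698) and no array block (0.0767). Over all alternatives the adjusted p ran from 1.82e-16 to 1.00.

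Interferon response and cholesterol synthesis genes lay above other genes with both plasmids, and cell cycle and stress genes below. Of 34 interferon response genes, 27 were above 0 (median 0.16, list adjusted p = 5.39e-06), among them SAMD9 (0.51 ± 0.08), IFIT1 (0.70 ± 0.11) and IFIT2 (0.65 ± 0.11), although the list value turned from 0.20 to -0.25 in the value table read by column name. Adjusted over the list alone, 12 of them rose and 1, OAS3 (-0.38 ± 0.13), fell. In that table the columns named PRC+ERRalpha hold Cy3 and those named control Cy5 channels. The list's dye effect, Cy5 minus Cy3, is 0.46, so the turn to -0.25 does not test the plasmids. Of 23 cholesterol synthesis genes, 19 were above 0 (median 0.17, adjusted p = 0.00780). Adjusted over the list alone, 7 rose, with SQLE, the squalene epoxidase gene (0.63 ± 0.11), STARD4 (0.36 ± 0.09) and LSS (0.37 ± 0.10) first, and PMVK (-0.42 ± 0.09) fell. Of 30 genes of the integrated stress and unfolded protein response, 19 were below 0 (median -0.18, adjusted p = 0.0359). Adjusted over the list alone, 11 fell, among them STC2 (-0.72 ± 0.12), the amino acid transporter gene SLC7A5 (-0.44 ± 0.09) and ASNS (-0.53 ± 0.11), and 2 rose, ATF3 (0.39 ± 0.10) and PDIA4 (0.26 ± 0.09). Of 40 cell cycle genes, 28 were below 0 (median -0.08, adjusted p = 0.0171), with FOXM1 (-0.48 ± 0.10), CDC25A (-0.39 ± 0.10) and BUB1B (-0.36 ± 0.09), and 0 passed adjusted over the list alone. These values are for each gene's brightest probe: other probes gave -0.10 to 0.05 for LSS, -0.07 to 0.09 for SAMD9, -0.05 for STC2, -0.13 for SLC7A5, -0.17 for CDC25A, 0.01 for OAS3 and 0.08 for ATF3 (A_24_P33895). The counts adjusted over a list alone come from lists called in the same data, so they are no further support for those lists. Over all genes, 0 members of the 4 lists passed by limma, while with an intensity trend SAMD9, IFIT1, IFIT2, SQLE and STC2 passed (adjusted p = 0.0394 to 0.0473). Without the array of ERRalpha replicate 2 and PRC replicate 2, these 5 (0.00178 to 0.0123), ASNS (0.0174) and SLC7A5 (0.0497) passed, and in the value table read by column name ASNS did (0.00411). With an estimated correlation, 0 of the 4 lists passed, each with an adjusted p of 0.532. Of 24 alternatives, 5 ended the calls of cell cycle and stress genes, 4 that of interferon and 3 that of cholesterol genes. The count of 4 fell to 0 without control replicate 2 or PRC+ERRalpha replicate 1, the interferon list then having an adjusted p of 0.141 and 0.0661, and the cholesterol list value fell from 0.13 to 0.01 without that control. ERRalpha target genes gave a median of 0.04 (adjusted p = 0.721). LDHB (-0.42 ± 0.11, adjusted p = 0.181), LDHA (-0.32 ± 0.12, adjusted p = 0.225), CYCS (0.16 ± 0.11), TFAM (-0.13 ± 0.10), NRF1 (-0.05 ± 0.08), SLC16A1 (0.03 ± 0.08) and PDK4 (-0.13 ± 0.09) did not pass. In the value table read by column name LDHB (-0.49, adjusted p = 0.00843) and SLC16A1 (0.28, 0.0353) did, but the columns compared there differ in dye. The direction differed between probes, with -0.45 and 0.08 from the other LDHA probes, 0.00 and 0.12 from those of TFAM and -0.04 from that of CYCS.

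**Figure D2:**
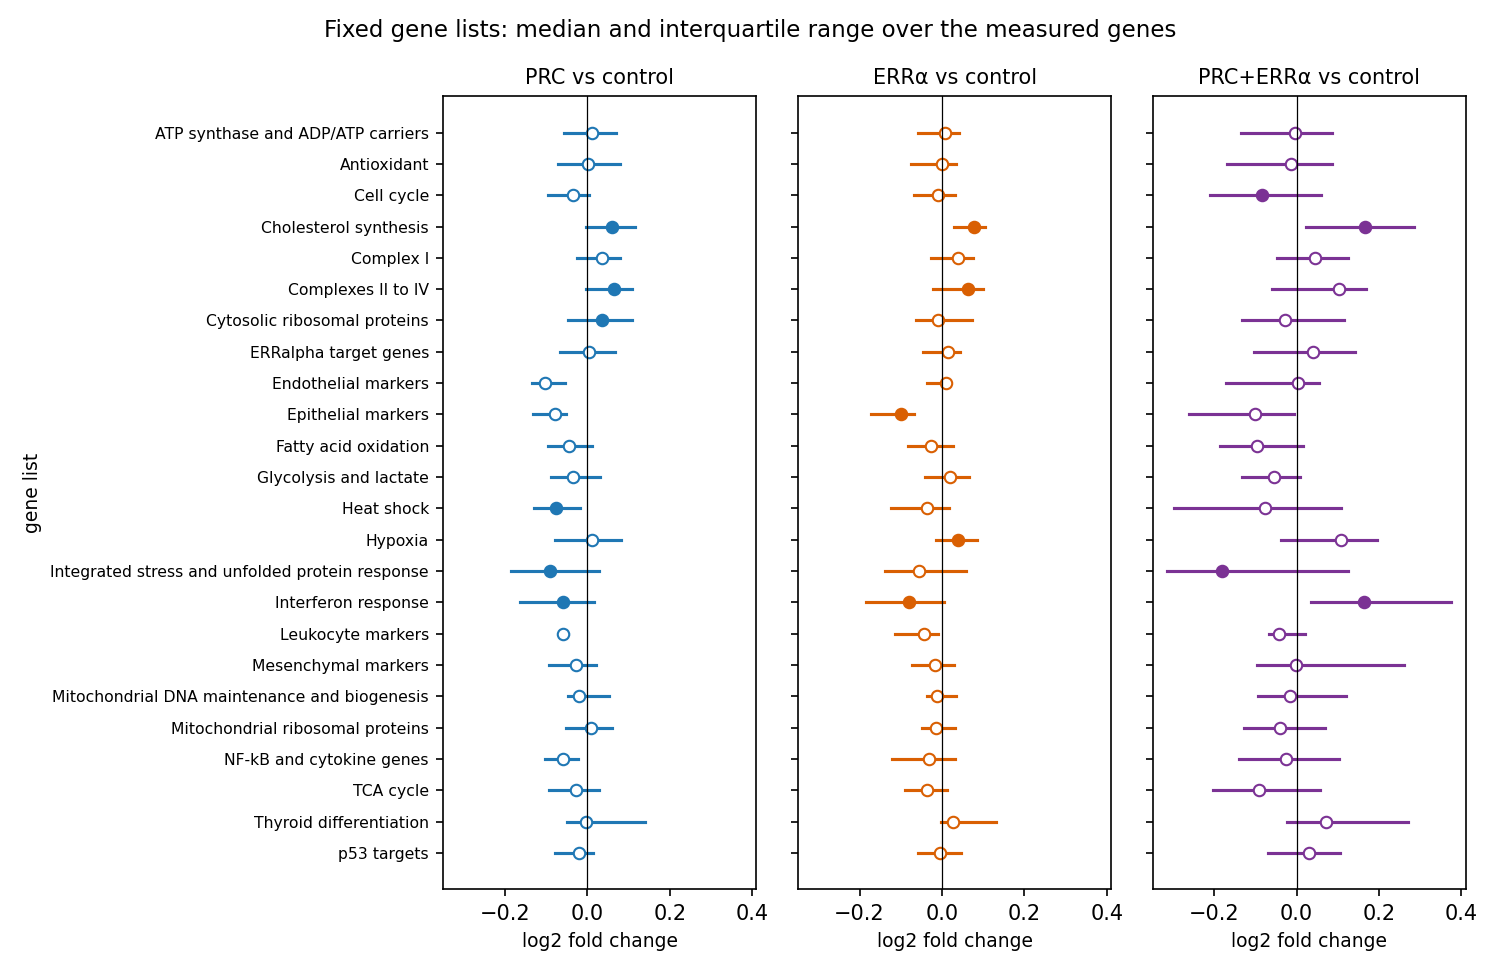
Median (point) and interquartile range (bar) of the log2 fold change over the measured genes of each of 24 fixed lists, against control, in 3 panels by plasmid; filled points passed an adjusted p of 0.05 with a preset correlation. Interferon response medians are -0.06, -0.08 and 0.16, and 0 lists passed with an estimated correlation. In the value table read by column name, the interferon list turned to 0.24 for ERRalpha and -0.25 for PRC+ERRalpha. Those columns mix groups and, for PRC+ERRalpha against control, dyes, so the turns do not test these medians.

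**Figure D3:**
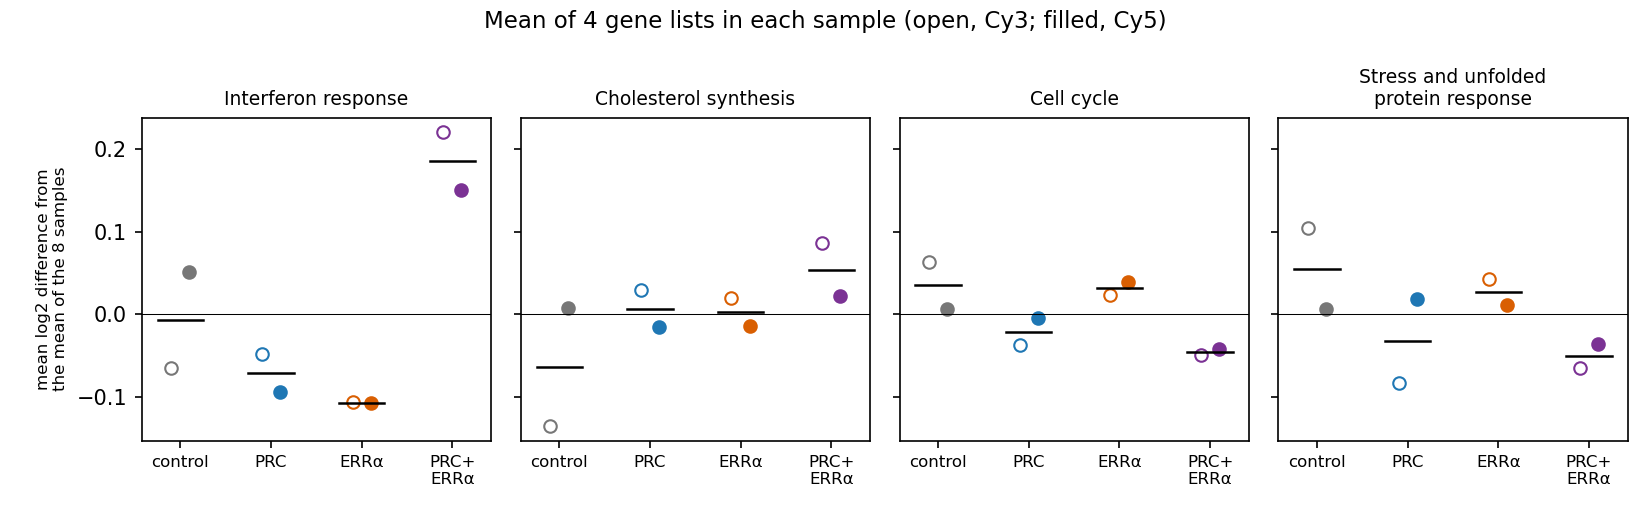
Mean dye-adjusted log2 difference of 4 gene lists from the mean of the 8 samples, 1 point per sample (open for Cy3, filled for Cy5), with the group mean as a bar. Interferon response genes lie at 0.22 and 0.15 in the PRC+ERRalpha samples and at 0.05 or below in the other 6. In the value table read by column name the list's difference from control turned to -0.25, but those columns differ in dye.

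Between the transfected groups, PPRC1 and CSH1 were higher with the PRC plasmid than with ERRalpha alone, and BX372426 and ADGRG1 were higher with both plasmids than with PRC alone. ADGRG1 was 2.47-fold higher in PRC+ERRalpha than in PRC cells (log2 difference 1.30 ± 0.11 SE, adjusted p = 0.0208), and BX372426, at background in PRC cells, was the other of the 2 called probes (at least 8.76-fold higher, adjusted p = 0.00282). CSH1 (2.44 ± 0.20 and 2.47 ± 0.20) and PPRC1 (2.48 ± 0.21) were higher in PRC+ERRalpha than in ERRalpha cells, each with an adjusted p of 0.0126. The other 2 of the 5 called there were transcripts without a current gene name, chosen after their values were seen, THC2664215 (0.87 ± 0.09) and THC2718728 (0.84 ± 0.09), each with an adjusted p of 0.0321. Another THC2718728 probe (A_32_P133038) gave 0.83 ± 0.10 (adjusted p = 0.0662). In PRC against ERRalpha cells, CSH1 (2.15 ± 0.20 and 2.17 ± 0.20) and PPRC1 (2.18 ± 0.21) were higher, each with an adjusted p of 0.0265, and BX372426 was at least 7.32-fold lower (adjusted p = 0.00214).

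The calls between transfected groups depended on samples and on processing. The 3 counts of 2, 5 and 4 probes became 0 without PRC+ERRalpha replicate 1, and without PRC replicate 2 they became 30, 6 and 31. Against PRC, the ADGRG1 call ended without either control (adjusted p = 0.189), PRC replicate 1 (0.170), PRC+ERRalpha replicate 1 (0.387) or replicate 2 (0.235), and that of BX372426 without the last pair (0.333 and 0.229). Against ERRalpha, those of CSH1 and PPRC1 ended without ERRalpha replicate 1 (0.164) or PRC+ERRalpha replicate 1 (0.292), and those of both THC transcripts without either control (0.203) or any ERRalpha or PRC+ERRalpha sample (0.0945 to 0.350). Between PRC and ERRalpha, those of CSH1 and PPRC1 ended without either control (0.102), ERRalpha replicate 2 (0.821 to 0.828) or either PRC+ERRalpha replicate (0.144, which also ended that of BX372426). Agilent's processed signals, loess only and log ratios ended all calls in these 3 comparisons, with adjusted p from 0.0802 to 1.00. The ADGRG1 call against PRC also ended with no array block (0.218), no background subtraction (0.0629), no dye term (0.181), no filter (0.0571) and the value table read by column name (0.708) or placed by channel (0.0605). Against ERRalpha, those of CSH1 and PPRC1 ended with no array block (0.211), no dye term (0.270) and no filter (0.0513), and those of the THC transcripts with the same (0.426, 0.911 and 0.0580), with no background subtraction (0.0706 and 0.132) and, for THC2718728, with quantile normalization alone (0.0955). Between PRC and ERRalpha, those of CSH1 and PPRC1 ended with no array block (0.547), no background subtraction (0.0728), no dye term (0.863), no filter (0.0893) and, for A_24_P211044 and PPRC1, the table placed by channel (0.0778), and that of BX372426 with no dye term (0.0614). Over all alternatives the adjusted p ran from 5.38e-11 to 0.760 for CSH1 and PPRC1 against ERRalpha, and from 3.86e-05 to 1.00 for ADGRG1. In the value table read by column name, CSH1 (A_24_P211044) and PPRC1 turned to -1.28 and -1.33 in PRC+ERRalpha against ERRalpha and to -1.74 and -1.67 in PRC against ERRalpha, and THC2664215 turned to -0.27. With loess only, the median over all probes in PRC+ERRalpha against ERRalpha moved from 0.01 to -0.13.

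Averaged over the other plasmid, the PRC plasmid raised 6 probes and lowered 2. Beside CSH1 (2.41 ± 0.13 and 2.45 ± 0.13 SE, adjusted p = 3.60e-04) and PPRC1, SNX5, a sorting nexin gene, rose 1.48-fold (0.57 ± 0.05, adjusted p = 0.0270; hg18 chromosome 20, 17896368 to 17896427). The brighter SNX5 probe, A_23_P131954, gave 0.08 ± 0.09 with PRC and 0.21 ± 0.09 with both plasmids against control and did not pass. The other 4 carry no current gene name and were chosen after their values were seen. THC2664215 (0.53 ± 0.06, adjusted p = 0.0312) and THC2718728 (0.48 ± 0.05, adjusted p = 0.0466) rose, and BC000228 (-0.55 ± 0.06, adjusted p = 0.0272) and A_24_P802562 (-0.44 ± 0.05, adjusted p = 0.0460) fell. The ERRalpha plasmid raised 3 probes and lowered 0, against 712 higher and 442 lower at an unadjusted p under 0.05 by limma. They were BX372426 (adjusted p = 2.17e-04, with no value given since PRC cells were at background), ADGRG1 (1.16 ± 0.08, adjusted p = 0.00312) and HES1 (0.88 ± 0.08, adjusted p = 0.0164). All 4 ERRalpha plasmid samples lay above the other 4 for these 3 probes. The PRC count was 129 without PRC replicate 2 and 2 without PRC+ERRalpha replicate 1, and of the runs with 1 sample left out, SNX5 and the 4 probes without a name kept their calls only in that without PRC replicate 2, with adjusted p from 0.0680 to 0.940 in the other 7. Of 20 to 22 alternatives, 13 ended the calls of SNX5 and BC000228, 14 that of THC2664215 and 15 those of THC2718728 and A_24_P802562. Beside left-out samples these were Agilent's processed signals (adjusted p = 0.608), loess only, log ratios and no dye term (1.00 each) and no array block (0.738 to 1.00) for all 5. For all but SNX5 they also included no background subtraction (0.0525 to 0.182), and for THC2718728 and A_24_P802562 no filter (0.0636 and 0.0534) and quantile normalization alone (0.180 and 0.0711). The CSH1 calls ended with Agilent's processed signals (0.608) and loess only (0.225). In the value table read by column name, SNX5 turned to -0.26, CSH1 (A_24_P211044) to -0.18 and THC2664215 to -0.09. The ERRalpha count was 15 without PRC replicate 2, 0 without PRC+ERRalpha replicate 2, and 1 without control replicate 2, ERRalpha replicate 2 or PRC+ERRalpha replicate 1. The BX372426 call ended without PRC+ERRalpha replicate 2 (adjusted p = 0.113) and with Agilent's processed signals (1.00), in a range from 1.20e-11. That of ADGRG1 ended without control replicate 2 (0.163), ERRalpha replicate 2 (0.0671) or PRC+ERRalpha replicates 1 (0.0849) or 2 (0.154), and with Agilent's signals (0.814), loess only (0.179), log ratios (1.00) and the value table (0.238), in a range from 7.84e-05. That of HES1 ended without control replicates 1 (0.0500) or 2 (0.258), PRC replicate 2 (0.0574), ERRalpha replicate 2 (0.223) or PRC+ERRalpha replicates 1 (0.0849) or 2 (0.434), and with Agilent's signals (0.814), loess only (0.0884), log ratios (1.00), no array block (0.125) and no dye term (0.781), in a range from 0.00134.

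Whether the effect of the PRC plasmid differed with ERRalpha present was tested as an interaction. If the combined transfection held more DNA in all, which the protocol wording leaves open, the interaction holds any effect of that amount too. By limma 0 probes passed, against 519 higher and 78 lower at an unadjusted p under 0.05, fewer than the 1343 that chance gives. Without PRC replicate 2 the count was 26 and without control replicate 2 it was 2. Interferon response genes had an interaction above 0 in 34 of 34 measured members (median 0.34, list adjusted p = 9.62e-30), among them MX1 (1.03 ± 0.14 SE), IFI44 (0.77 ± 0.14) and IFIT1 (0.86 ± 0.17). Adjusted over the list alone, 15 of these passed, and over all genes 0. An interaction above 0 is not itself a rise, and OAS3 was lower than control with both plasmids (-0.38 ± 0.13). The list did not pass with an estimated correlation (adjusted p = 0.194) or in the value table read by column name (list value 0.13 against 0.37, adjusted p = 0.0652), and without any 1 sample it passed with the preset correlation. Cytosolic ribosomal protein genes (median -0.05, adjusted p = 0.00338), glycolysis genes (median -0.06, adjusted p = 0.0250) and mitochondrial ribosomal protein genes (median -0.03, adjusted p = 0.0252) were below other genes, but the cytosolic ribosomal list value turned from -0.06 to 0.10 with loess only and to 0.03 in the value table placed by channel, and the other 2 lists turned to 0.01 and 0.03 in that table read by column name. With loess only, the median interaction over all probes moved from 0.02 to -0.26. None of these 3 passed with an estimated correlation (adjusted p = 0.194, 0.475 and 0.583), and of 24 alternatives 7, 14 and 14 ended their calls.

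In the 3 comparisons with control, 15 of the 24 lists did not pass. The lists of energy metabolism among them were Complex I (37 genes, smallest adjusted p = 0.0629), ATP synthase and ADP/ATP carriers (20 genes, 0.538), the TCA cycle (23 genes, 0.0657), glycolysis and lactate (27 genes, 0.0657), fatty acid oxidation (24 genes, 0.0657), mitochondrial DNA maintenance and biogenesis (28 genes, 0.620), mitochondrial ribosomal proteins (78 genes, 0.215) and ERRalpha target genes (24 genes, 0.579). The other 7 were antioxidant genes (26 genes, 0.382), NF-kB and cytokine genes (23 genes, 0.0629), p53 targets (19 genes, 0.579), thyroid differentiation genes (9 genes, 0.155) and the mesenchymal (17 genes, 0.406), leukocyte (6 genes, 0.247) and endothelial (6 genes, 0.111) markers. Their medians ran from -0.10 for endothelial markers in PRC cells to 0.07 for thyroid differentiation genes. A p that misses the threshold does not show that a list was unchanged.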

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

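The tests of the CSH1, BX372426 and interferon patterns, and those of the gene lists in the interaction, were chosen after the results were seen, and the counts over other splits of the samples before.

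The deposited value table, which the comparisons did not use, held a signal for PPRC1 where its column names put none. PPRC1 was 2.30 log2 units higher in the columns named for ERRalpha than in those named for control, against 0.68 for the columns named for PRC and 1.21 for those named for PRC+ERRalpha. In the scanner channels, PPRC1 was high in the 4 samples with the PRC plasmid.

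In 4 gene lists, the effect of the PRC plasmid differed with and without ERRalpha by the test of the interaction with a preset correlation. The median interaction was 0.34 (log2) for interferon response genes, -0.0517 for cytosolic ribosomal proteins, -0.0586 for glycolysis and lactate and -0.0322 for mitochondrial ribosomal proteins. None of these calls held with an estimated correlation, where the adjusted p was 0.194, 0.194, 0.475 and 0.583, and the cytosolic ribosomal list value turned to 0.10 with loess only, while the last pair turned to 0.01 and 0.03 in the value table read by column name.

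Over the 4 samples with the PRC plasmid, the CSH1 level (mean of both called probes) minus the PPRC1 level had an SD of 0.0307, against 0.464 for PPRC1 itself. The ERRalpha samples (9.25 and 9.30) lay above the controls (8.62 and 8.73) as well, though the fitted difference of either probe (0.23 ± 0.22 and 0.27 ± 0.22 SE) did not pass. A candidate explanation, as a hypothesis, is that the PRC plasmid holds sequence that these probes read, such as a growth hormone family end region used in expression vectors, but the labels do not give the vector. A higher transcript of the cell's own CSH1 gene stays open, since the other tested CSH1 probe (-0.0520 ± 0.0792 SE) was well above background in 3 of 8 channels and 2 further probes were not tested. Neither test separates the plasmid from an own transcript that follows PPRC1 as closely.

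The BX372426 probe, near the ESRRA probe, was higher in every sample with the ERRalpha plasmid, its lowest such sample lying 2.47 log2 units above the highest other sample. The tables argue against a higher transcript of the cell's own ESRRA gene as read by its probe (0.0815 ± 0.0656 SE). They also argue against a rise of the whole neighbourhood, since the 4 probes of TRMT112 and PRDX5 moved by at most 0.120 in size. A candidate explanation that stays open, as a hypothesis, is plasmid sequence read by this probe. The gap of 2.47 follows the plasmid whether the source is the plasmid or the cell, so it cannot separate them.

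Interferon response genes had an interaction above 0 in the fitted model, from which a dye effect common to all arrays cancels, since each group lay once in each dye. An effect of whole arrays need not cancel. PRC and ERRalpha replicates 2, on 1 array, both enter with minus, and control and PRC+ERRalpha replicates 2, on another, with plus. On the other arrays such an effect cancels, and the list's Cy5 minus Cy3 differences were 0.56 (control minus PRC) and 0.14 (ERRalpha minus PRC+ERRalpha). Their difference is an interaction above 0 too, but it rests on 1 sample per group. The first test compared each combined sample with the sample on its own array and gave -0.14 with Cy3 (8 of 34 genes higher) and 0.68 with Cy5 (31 of 34), but the list's dye effect (0.464, against 0.0111 for other genes) is above its mean fitted difference from ERRalpha (0.31), so opposite signs arise with or without a rise and the test decides nothing. The second test, devised after that outcome was seen because of this dye effect, took off the dye difference of the 2 arrays without a combined sample and left departures of 0.38 (31 of 34 genes above 0) and 0.16 (25 of 34). Its 95% prediction bound of 0.950 rests on those 2 arrays and is too wide for the test to decide. A dye effect that differed between arrays (those 2 differed by 0.0864) stays open. So does a chance shift of genes that vary together (adjusted p = 0.194 with an estimated correlation). Plasmid amount stays open too, since the protocol wording does not settle whether the combined transfection held more DNA in all than the others. If it did, the combination and the DNA amount changed together, and none of these tests separates them.

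The real splits by the PRC plasmid and by the ERRalpha plasmid called 3 probes each in a model with the split, dye and array block. Among the 35 splits of the 8 samples into 4 and 4, 5 called as many, both real ones included. The others were the split by dye (8206, fitted without a dye term, and the highest), a split that differs from it in 1 array's samples (1435) and 1 that keeps each array's samples together (4). With the dye split above either real split, the share among the 35 could not fall under 0.05, so that count cannot test chance. Without the dye split and the other plasmid's split, 3 of 33 called as many, the real one included. The others among these follow the dye in part or keep arrays together, so they do not measure chance alone. Chance is thus not excluded for either count. The count of 8206 points to a structure of the samples by dye. The 1435 come from a split fitted with a dye term. That split sets PRC+ERRalpha replicate 2 minus control replicate 2, on their shared array, against the dye difference of the other arrays. It can thus hold a plasmid effect as well as an array effect, and which of them gave the 1435 was not tested.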

How the results depend on the processing

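The value table placed by channel, the array left out and the lists outside the comparisons with control were chosen after seeing the data. Where a value differs here, the cause was not tested unless the alternative itself shows it. Of the values for single genes, 2103 stayed on their side, 281 lost and 45 gained a call, 114 turned sign with no call on either side and 11 reversed. Of those for lists, 299 stayed, 138 lost a call and 17 reversed. Counts are given in the order PRC, ERRalpha and PRC+ERRalpha against control, PRC+ERRalpha against PRC, PRC+ERRalpha against ERRalpha, PRC against ERRalpha, PRC average and ERRalpha average, with 2, 1, 6, 2, 5, 4, 8 and 3 probes called, and 6, 5 and 4 lists in the first 3.

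With Agilent's processed signals, limma called 0 probes in all 8 (322 to 2476 at an unadjusted p under 0.05) and 0 of the transfected genes. With loess only it called 0 in all but the ERRalpha average (1), against 97 to 1146 unadjusted, and 0 of the transfected genes, 3 and 8 lists for ERRalpha and PRC+ERRalpha, and list values of -0.0378 (PRC) and 0.10 (interaction) for cytosolic ribosomal proteins. From here on, a count is given only where it differs by more than 1.5 times. Without background subtraction these were 0, 1, 3, 1 and 4 (PRC, against PRC, against ERRalpha, PRC against ERRalpha, PRC average). Without a filter they were 0, 1, 0 and 1 in the first 4 of these, and 10 lists for PRC+ERRalpha. With a filter on all channels they were 0 (ERRalpha) and 1 (against PRC). Without a dye term they were 0, 1, 0, 0 and 3, with 3 and 0 lists (PRC, ERRalpha). With a replicate block, 8 passed against ERRalpha. Without an array block they were 0 and 0 (PRC, ERRalpha), 1, 0, 1 and 3, with 3 lists for ERRalpha. With log ratios, which leave 1 residual degree of freedom, they were 0 in the first 6 (13 to 67 unadjusted), then 3 and 1, with 2, 2 and 7 lists. With an intensity trend they were 4, 2 and 56 in the first 3 (38 higher and 18 lower of the 56) and 12 against ERRalpha. With an estimated correlation, 0, 0 and 0 lists passed.

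In the value table by column names the counts were 3143 (PRC), 2599 (PRC+ERRalpha), 0, 3589, 4956, 6332 and 1, with 0 transfected genes and 2 and 10 lists (ERRalpha, PRC+ERRalpha). There, 5 of 8 columns hold another group's channel, which by construction mixes the groups. The columns named control or ERRalpha hold Cy5 channels and those named PRC or PRC+ERRalpha hold Cy3 channels, while the dye term followed the labels. The large counts for PRC, PRC+ERRalpha, PRC+ERRalpha against ERRalpha, PRC against ERRalpha and the PRC average thus set Cy3 against Cy5. Neither they nor the reversals test the plasmids. List values reversed to -0.0945 (Complexes II to IV), -0.37 (cytosolic ribosomal) and -0.00401 (heat shock, by its test) for PRC, to -0.00690 (Complexes II to IV), 0.24 (interferon) and -0.0359 (cholesterol) for ERRalpha, to -0.25 (interferon) for PRC+ERRalpha, and to 0.00917 (glycolysis) and 0.0279 (mitochondrial ribosomal) in the interaction. Reversed genes were CSH1 (A_24_P211044; -1.28, -1.74 and -0.18) and PPRC1 (-1.33, -1.67 and -0.20) against ERRalpha, in PRC against ERRalpha and on PRC average, THC2664215 (-0.27 and -0.0926), SNX5 (-0.26), RPLP1 (-0.51) and RPS10 (-0.37). Placed by channel, the counts were 1, 0, 3, 0, 3, 0, 5 and 1, with 3 and 2 lists (ERRalpha, PRC+ERRalpha), and the cytosolic ribosomal interaction was 0.0310. Without the array of ERRalpha replicate 2 and PRC replicate 2, whose 51.0% above background limits what can be seen there, the counts were 311, 78, 378, 198, 149, 217, 950 and 191, with 78 in the interaction and 1 list each for PRC and ERRalpha.

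Leaving out each sample in turn, the counts ran from 0 to 63 (63 without PRC replicate 2, 8 without control replicate 1), 0 to 9 (9 without control replicate 1), 0 to 16, 0 to 30, 0 to 9, 0 to 31, 2 to 129 and 0 to 15, from 0 to 26 in the interaction, and from 0 to 1 for the transfected genes. Lists ran from 1 to 7, 1 to 3 and 0 to 7. List values ran from -0.13 to 0.0208 (interferon), -0.15 to 0.0237 (integrated stress) and -0.0137 to 0.17 (cholesterol) for PRC, and from -0.0297 to 0.16 (cholesterol) and -0.23 to 0.0115 (epithelial) for ERRalpha. Replicates with the same number did not resemble each other beyond shared arrays (correlation of replicate differences across genes 0.06 and -0.21 between groups that share none, 0.36 to 0.59 otherwise), so the numbers were not taken as pairs. A block for slide or scan was not run.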

Other observations

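The tests of the gene lists between transfected groups and on the average effects were chosen after the results were seen. With a preset correlation, 7 of 24 lists passed in PRC+ERRalpha against PRC, 4 in PRC+ERRalpha against ERRalpha, 1 in PRC against ERRalpha, 6 for the PRC average and 7 for the ERRalpha average, and 0 passed in any of these with an estimated correlation. Adjusted over the list alone, 12 of 34 interferon response genes passed in PRC+ERRalpha against PRC (adjusted p of the list = 9.98e-17, or 0.368 with an estimated correlation) and 20 against ERRalpha (4.94e-18, lost with an estimated correlation too). These lists were not run under the other settings, so no direction is claimed for these differences.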
